A study of Homo sapiens with 12 samples.

How the data were processed

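Polyadenylated RNA was sequenced from 12 libraries: 4 groups of KMS-11 TKO cells, 3 biological replicates each, labelled TKO (no vector), WT, D1240A and F1295A. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, inspected with FastQC 0.11.4, aligned to GRCh38 with STAR 2.7.9a and quantified with RSEM 1.3.1, and differential expression was run with DESeq2. The deposited table holds 1 FPKM value per gene and library, that is, fragments scaled by gene length and by the mapped total. The annotation release and the strand setting are not given in the sources used here. The table lists 60504 features, of which 56996 (94.2%) have an Ensembl identifier in GENCODE release 29, used here for names, classes and coordinates. The other 3508 carry placeholder names and were kept out of the named genes. No 2 libraries were identical. The sequencing depth is unknown, so no value carries a counting error, and precision was judged from the spread of the 3 replicates of each group.

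What follows was computed from the deposited FPKM. A count-based test had been planned before the data were examined. FPKM are not counts, so limma was used instead, and CPM in the planned rules was replaced by FPKM. Ribosomal, small nuclear, small nucleolar, miscellaneous and similar structural RNA features, 7089 in all, were left out, a choice made after the data were seen because 1 library held large amounts of them. Each library was rescaled by a trimmed mean of log2 ratios to the mean library, over genes with a mean of at least 1 FPKM and with 30% trimmed from each side. Genes with at least 0.5 FPKM in at least 3 libraries were tested, 14391 in all. The 12 libraries were fitted in 1 model with limma 3.58.1 (R 4.3.3) on log2(FPKM + 0.5), with group as the only factor and a variance trend over mean expression. The 4 groups thus share their estimate of spread. The 6 pairs of groups were compared. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over all tested genes), with no minimum fold. Rescaling fixes the center of each library, so a change shared by all genes could not be seen.

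Gene lists were fixed before the data were examined: 35 lists with 1323 genes, 1318 of them found in the table. Lists with at least 5 tested genes, 30 in all, were tested with camera, which asks whether a list moved relative to the other genes, with the correlation between genes preset to 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with the correlation estimated from the libraries is given beside each call. Fisher's exact test compared called and not called genes of a list with those of all other genes, and fry served as another test. In counts of list members, "rose" and "fell" mean called higher or lower in the group named first, over all tested genes, and a count adjusted over the list alone stands beside it.

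Genes were named from those picked by a rule. NSD2 came first. Then came, in each comparison, the 8 genes with the largest log2 change in each direction among called genes with all 3 libraries of one group above all 3 of the other, a mean over all libraries of at least 2 FPKM and a gene symbol. For each list, its 4 tested members with the smallest adjusted p followed, with every member of the H3K36 list.

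Slopes compare the change of a mutant from TKO with that of WT from TKO over all tested genes, after subtracting the variance and covariance that library spread and the shared TKO libraries add. Overlaps of calls were set beside the number expected of independent lists, and covariances beside those of 20 simulations of unchanged groups sharing the same controls. Medians were taken over 273 windows of 50 neighbouring tested genes, with 100 shuffles of the gene order as reference.

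The steps were tested on simulated data with the spread of these libraries and 100 changed genes per fold. Of genes changed 1.5-fold, 67% to 86% were called in the 6 comparisons, and of those changed 3-fold 97% to 99%, with 4 to 11 false calls. A true slope of 0.8 was read as 0.796 and 0.812, and as 0.753 without the correction. A list shifted by 0.3 was called, and 1 other list of 30 was called with it.

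Alternatives tried were median-ratio scaling, the values as deposited, no filter and a filter at 1 FPKM, pseudocounts of 0.1 and 1, library weights, structural RNAs kept, window medians removed, a replicate block, only the compared groups in the fit, at least 2-fold change, estimated correlation, fry, and each library left out. All 12 libraries were used. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.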

Results

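Polyadenylated RNA was sequenced from 12 libraries of TKO cells, which derive from the human multiple myeloma line KMS-11 and carry the genotype label WHSC1 +/-. WHSC1 is an older name of NSD2, an enzyme that methylates histone H3 at lysine 36, and KMS-11 is a myeloma line in which the t(4;14) translocation raises NSD2. The cells had no vector (TKO) or expressed wild-type NSD2 (WT), NSD2 with the substitution D1240A, or NSD2 with F1295A. Both substituted residues lie in the C-terminal part of the protein, after its catalytic SET domain. Each of the 4 groups had 3 biological replicates. A TKO line with an empty vector was not analysed here, so every comparison with TKO also compares cells with and without a vector. Each library held 11963 to 12297 genes at 1 FPKM or more. The number of reads per library is not given in the sources used here, so the depth is unknown and no counting intervals are given. Values are FPKM after rescaling between libraries, as mean ± SD with n = 3 libraries per group, and changes and medians are on the log2 scale. In pairs of values the first is of the group named first in the comparison.

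D1240A replicate 2 stood apart in the RNA classes it held. Ribosomal RNA features made up 51.4% of its FPKM sum as deposited, against 0.133% to 0.995% in the other libraries, and small nuclear RNAs summed to 90165 FPKM, against 66.8 to 307. Features classed as long intergenic RNA, which were tested, summed to 257696 FPKM, against 4337 to 5793. Transcripts of replication-dependent histone genes, which carry no poly(A) tail, were higher in it too. Their median log2 difference from the mean of the other D1240A libraries was 3.97, and 33 of 34 tested histone genes lay above 0. Its log2 scaling factor was -0.30, against -0.00 to 0.06 in the other libraries.

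**Figure D1:**
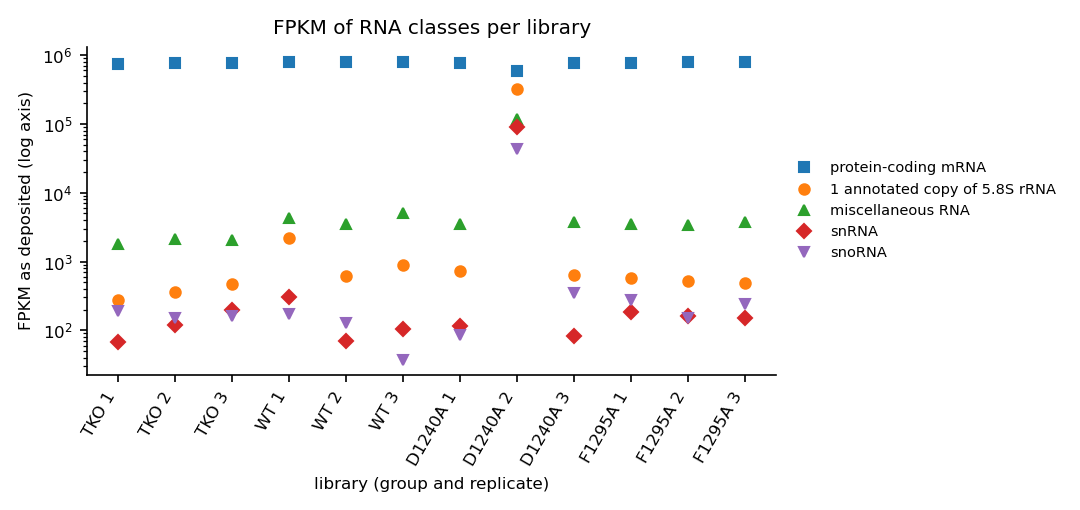
FPKM as deposited (vertical, log axis) of 5 RNA classes in each of the 12 libraries (horizontal): protein-coding genes, 1 annotated 5.8S ribosomal RNA copy, miscellaneous RNAs, small nuclear RNAs and small nucleolar RNAs. D1240A replicate 2 has the highest value of each structural class.

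NSD2 itself (ENSG00000109685) was read in every library. It measured 59.0, 58.7 and 62.7 FPKM in the 3 TKO libraries, 189.1, 187.7 and 195.1 in WT, 242.0, 258.7 and 249.9 in D1240A, and 171.7, 161.3 and 159.3 in F1295A. WT and TKO had means of 191 ± 3.90 against 60.1 ± 2.25, a log2 change of 1.66 (adjusted p = 5.2e-11). D1240A carried more NSD2 mRNA than WT, 250.2 ± 8.33 FPKM, a log2 change of 0.39 (adjusted p = 5.6e-05). F1295A carried less than WT, 164 ± 6.65 FPKM, a log2 change of -0.22 (adjusted p = 0.0134). This last call was lost without WT replicate 1 (adjusted p = 0.0513), WT replicate 3 (0.0610), F1295A replicate 2 (0.0647) or F1295A replicate 3 (0.0575), and on the values as deposited (0.204). Each of these changes separated all 3 libraries of one group from all 3 of the other. Reads from the vector and from the chromosomal gene were not told apart, and RNA levels do not measure the protein.

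WT against TKO asks what wild-type NSD2 changes in cells that have lost 1 copy. The genes that rose most went from near 0 to clear expression. LRMP, an endoplasmic reticulum protein of lymphoid cells (ENSG00000118308, chromosome 12, 25004342 to 25108334), measured 20.9 ± 0.356 against 0.0288 ± 0.0288, log2 change 5.34, adjusted p = 3.7e-14. POPDC3 (ENSG00000132429, chromosome 6, 105158280 to 105179995) measured 26.4 ± 0.193 against 0.224 ± 0.0467, log2 change 5.22, adjusted p = 3.7e-14. The neuronal sodium channel SCN3A reached 12.9 ± 0.538 against 0.0768 ± 0.00935, log2 change 4.54. The red-cell glycophorin GYPC reached 15.4 ± 0.650 against 0.237 ± 0.0727, log2 change 4.44, and the collagen lysyl hydroxylase PLOD2 10.8 ± 0.620 against 0.106 ± 0.0628, log2 change 4.23. HBE1, embryonic epsilon globin, was listed at 0 in all 3 TKO libraries and at 8.35, 8.46 and 6.20 FPKM in WT (adjusted p = 4.3e-10), though its annotated span overlaps other globin genes. MAGEA3, a cancer-testis antigen close in sequence to MAGEA6, was listed at 0 in TKO and at 7.24, 8.01 and 6.87 FPKM in WT (adjusted p = 5.4e-12).

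Among the genes that fell most was APOBEC3G, a cytidine deaminase with close paralogs (ENSG00000239713, chromosome 22, 39077005 to 39087743), at 0.117 ± 0.0926 against 10 ± 0.254, log2 change -4.10, adjusted p = 3.1e-10. ADTRP, a regulator of coagulation (ENSG00000111863, chromosome 6, 11712054 to 11807046), measured 0.839 ± 0.118 against 22 ± 0.258, log2 change -4.07, adjusted p = 8.9e-11. The receptor TNFRSF18 measured 3.82 ± 0.614 against 35.4 ± 0.911, log2 change -3.07, and the cytokine receptor subunit CSF2RB 0.558 ± 0.0470 against 6.13 ± 0.318, log2 change -2.65. The matrix protease MMP9 measured 0.611 ± 0.134 against 6.14 ± 0.491, log2 change -2.58, and delta globin, HBD, 0.787 ± 0.206 against 8.14 ± 1.04, log2 change -2.75. LUZP6, annotated at 135927274 to 135927450 on chromosome 7 within the gene MTPN, was listed at 0 in WT and at 8.24, 12.8 and 24.7 FPKM in TKO (adjusted p = 0.00108).

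Cell adhesion genes, the subject of the series title, changed in both directions. Of 15 tested cadherins and protocadherins, 9 rose, 4 fell and 2 were not called, with 14 called when adjusted over the list alone. The cadherin list's median was 0.66 (adjusted p = 0.00605, and adjusted p = 0.162 with an estimated correlation, and adjusted p = 0.0132 by Fisher's exact test). CDH17, a cadherin of intestinal epithelium (ENSG00000079112, chromosome 8, 94127171 to 94217303), rose to 80.5 ± 1.45 against 6.68 ± 0.197, log2 change 3.5, adjusted p = 3.7e-14. The neural cadherin CDH2 rose to 10.1 ± 0.0320 against 1.03 ± 0.220, log2 change 2.80, and the desmosomal cadherin DSG2 and the planar polarity cadherin CELSR1 rose with log2 changes of 0.66 and 0.85. Of 53 clustered protocadherins 1 was tested, PCDHB14, which rose to 0.868 ± 0.141 against 0.483 ± 0.0890 FPKM. Of 13 tested integrins, 5 rose, 4 fell and 4 were not called, with 9 called when adjusted over the list alone. The integrin list's median was -0.08, the mean 0.16 and the tested direction higher (adjusted p = 0.572, and adjusted p = 0.265 by Fisher's exact test). ITGB7 (0.82) and ITGB1 (0.37) rose, and ITGAL (-0.89) fell. Of 35 tested immunoglobulin-like adhesion molecules and selectins, 8 rose, 12 fell and 15 were not called, with 21 called when adjusted over the list alone. The immunoglobulin-like list's median was 0.00, or -0.01 on the values as deposited, the mean -0.10 and the tested direction lower (adjusted p = 0.264, and adjusted p = 0.482 by Fisher's exact test). The lymphocyte ligand CD48 fell to 27.6 ± 0.379 against 89.9 ± 2.77, log2 change -1.69. L1CAM and NRCAM, adhesion molecules of neurons, fell by 2.18 and 1.18, and CNTN1, of the same kind, rose to 6.27 ± 0.136 against 0.291 ± 0.0445, log2 change 3.10.

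Matrix and cytoskeletal genes also moved both ways. Of 30 tested extracellular matrix genes, 14 rose, 7 fell and 9 were not called, with 21 called when adjusted over the list alone. The matrix list's median was 0.16 (adjusted p = 0.138, and adjusted p = 0.0656 by Fisher's exact test). COL19A1 (1.92) and MATN2 (0.84) rose, and COL6A1 (-2.57) fell. Of 52 tested genes of focal adhesion and actin linkage, 19 rose, 14 fell and 19 were not called, with 36 called when adjusted over the list alone. The focal adhesion list's median was 0.05 (adjusted p = 0.540, and adjusted p = 0.104 by Fisher's exact test). TES (1.16) and EVL (1.11) rose and moesin, MSN (-0.68), fell. Of 39 tested axon guidance genes, 16 rose, 5 fell and 18 were not called, with 22 called when adjusted over the list alone. The axon guidance list's median was 0.10 (adjusted p = 0.162). The ephrin receptor EPHB1 rose to 8.32 ± 0.267 against 0.999 ± 0.128, log2 change 2.56. Of 18 tested markers of epithelial-mesenchymal transition, 7 rose, 6 fell and 5 were not called, with 14 called when adjusted over the list alone. The transition marker list's median was 0.01, or -0.01 on the values as deposited (adjusted p = 0.540). Vimentin, VIM (0.86), and fibronectin, FN1 (1.54), rose, and S100A4 (-2.25) fell.

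**Figure D2:**
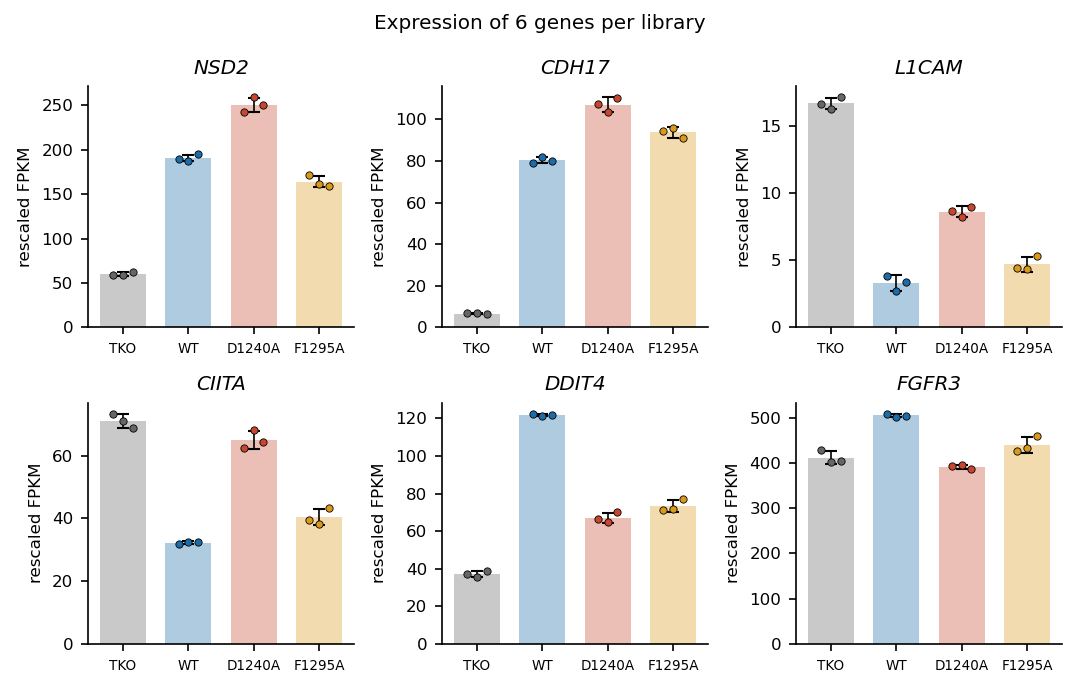
Rescaled FPKM (vertical) of NSD2, CDH17, L1CAM, CIITA, DDIT4 and FGFR3 in the 4 groups (horizontal); bars are means, error bars SD, n = 3, and points are libraries. CDH17 lies at 6.68 in TKO and 80.5, 107 and 93.7 in WT, D1240A and F1295A, and CIITA at 71.1, 32.3, 65.0 and 40.3.

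Genes tied earlier to t(4;14) myeloma or to NSD2 rose as a group. Of 18 tested, 14 rose, 2 fell and 2 were not called, with 17 called when adjusted over the list alone. The t(4;14) list's median was 0.58 (adjusted p = 9.9e-05, and adjusted p = 0.0660 with an estimated correlation). Carbonic anhydrase CA2 rose to 8.76 ± 0.547 against 0.682 ± 0.123, log2 change 2.97, adjusted p = 1.4e-10. The small GTPase RRAS2 (3.03) and the kinase PAK1 (2.88) rose as well. Of 20 tested plasma cell genes, 11 rose, 6 fell and 3 were not called, with 17 called when adjusted over the list alone. The plasma cell list's median was 0.35 (adjusted p = 0.0191, and adjusted p = 0.177 with an estimated correlation). The antibody joining chain JCHAIN rose to 3790 ± 116 against 1733 ± 109, log2 change 1.13, and the secretory regulator XBP1 to 429 ± 3.99 against 258 ± 4.26, log2 change 0.73. Of 10 tested B cell genes, 4 rose, 5 fell and 1 was not called, with 9 called when adjusted over the list alone. The B cell list's median was -0.30 (adjusted p = 0.540). CD37 (1.74) rose, and the transcription factors IRF8 (-1.87) and SPIB (-0.73) fell. Of 10 tested MAF targets, 4 rose, 2 fell and 4 were not called, with 9 called when adjusted over the list alone. The MAF list's median was 0.18 (adjusted p = 0.0696). Of 18 tested neighbours of NSD2 at 4p16.3, 4 rose, 5 fell and 9 were not called, with 9 called when adjusted over the list alone. The 4p16.3 list's median was -0.01, the mean 0.02 and the tested direction lower (adjusted p = 0.793). FGFR3, the receptor gene on the same translocation, rose to 505 ± 2.89 against 412 ± 14, log2 change 0.30.

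Polycomb (PRC2) members and other H3K27 enzymes fell. Of 14 tested PRC2 and H3K27 genes, 0 rose, 8 fell and 6 were not called, with 8 called when adjusted over the list alone. The PRC2 list's median was -0.19 (adjusted p = 0.00115, and adjusted p = 0.0372 with an estimated correlation). The catalytic subunit EZH2 fell to 67.8 ± 0.796 against 95.5 ± 1.77, log2 change -0.49, adjusted p = 7.1e-08, or -0.23 once the median of its window of neighbouring genes was removed, and PHF19 fell by 0.53. RBBP7 and KDM6A on the X chromosome fell by 1.12 and 0.89, and by 0.22 and 0.39 in the same way. Of 20 tested writers, erasers and readers of H3K36 methylation, 6 rose, 6 fell and 8 were not called, with 12 called when adjusted over the list alone. The H3K36 list's median was -0.02, the mean 0.06 and the tested direction lower (adjusted p = 0.864). Besides NSD2, NSD1 rose by 0.60, though with its window's median removed it changed by 0.02 and was not called. The DNA methyltransferase DNMT3A (0.38) rose, and DNMT3B (-0.77) and the demethylase KDM2A (-0.28) fell. Of the other called members, KDM4A, SETD3 and NSD3 rose and DNMT1, HDGFL2, ASH1L and PSIP1 fell, and with window medians removed only KDM4A and PSIP1 of these were called. Of 34 tested replication-dependent histones, 0 rose, 5 fell and 29 were not called, with 5 called when adjusted over the list alone. The histone list's median was -0.61 (adjusted p = 0.0855). HIST1H1C measured 202 ± 7.17 against 400.02 ± 6.70, log2 change -0.99. D1240A replicate 2, with its high histone reads, enters the spread of that test, and without it 22 histones fell and the adjusted p was 1.9e-06. Of 10 tested HOX genes, 2 rose, 0 fell and 8 were not called, with 2 called when adjusted over the list alone. The HOX list's median was 0.19 (adjusted p = 0.227).

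Stress and metabolic genes rose in WT. Of 33 tested unfolded protein response genes, 22 rose, 2 fell and 9 were not called, with 26 called when adjusted over the list alone. The unfolded protein list's median was 0.30 (adjusted p = 1.8e-08, and adjusted p = 0.0135 with an estimated correlation). The glutathione-degrading enzyme CHAC1 rose to 19.3 ± 0.425 against 2.30 ± 0.167, log2 change 2.82, adjusted p = 1.0e-11, SESN2 to 21.2 ± 0.873 against 4.32 ± 0.271, log2 change 2.17, and asparagine synthetase, ASNS, to 83.1 ± 1.25 against 37.6 ± 0.910, log2 change 1.13. Of 33 tested hypoxia and glycolysis genes, 28 rose, 1 fell and 4 were not called, with 31 called when adjusted over the list alone. The hypoxia list's median was 0.50 (adjusted p = 1.1e-08, and adjusted p = 0.0135 with an estimated correlation). The mTOR inhibitor DDIT4 rose to 122 ± 0.506 against 37.4 ± 1.52, log2 change 1.69, as did the glycolytic enzymes ALDOC (1.82) and ENO1 (0.73). Of 23 tested cholesterol synthesis genes, 19 rose, 2 fell and 2 were not called, with 21 called when adjusted over the list alone. The cholesterol list's median was 0.62 (adjusted p = 4.6e-08, and adjusted p = 0.0135 with an estimated correlation). INSIG1 (1.18), MSMO1 (1.26) and STARD4 (1.52) rose. Of 77 tested cytosolic ribosomal protein genes, 70 rose, 1 fell and 6 were not called, with 75 called when adjusted over the list alone. The ribosomal protein list's median was 0.47 (adjusted p = 6.9e-20, and adjusted p = 0.221 with an estimated correlation). RPL4 measured 2588 ± 28.9 against 1706 ± 46.3, log2 change 0.60, and reads of such genes are shared with pseudogenes.

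Cell cycle genes fell. Of 47 tested cell cycle genes, 4 rose, 32 fell and 11 were not called, with 37 called when adjusted over the list alone. The cell cycle list's median was -0.19 (adjusted p = 2.0e-06, and adjusted p = 0.0391 with an estimated correlation). Thymidylate synthase, TYMS, fell to 201 ± 3.88 against 289 ± 4.37, log2 change -0.53, and TOP2A (-0.58) fell. Of 41 tested genes of MYC and ribosome biogenesis, 12 rose, 8 fell and 21 were not called, with 20 called when adjusted over the list alone. The MYC list's median was 0.04 (adjusted p = 0.462). MYC rose to 238 ± 9.15 against 155 ± 1.07, log2 change 0.62. Of 74 tested nuclear genes of oxidative phosphorylation, 27 rose, 14 fell and 33 were not called, with 42 called when adjusted over the list alone. The oxidative phosphorylation list's median was 0.05 (adjusted p = 0.540). NDUFB8 (0.67, 0.34 with its window's median removed) rose and ATP5MF (-0.38, -0.14 with its window's median removed) fell. Of 13 tested mitochondrially encoded mRNAs, 0 rose, 3 fell and 10 were not called, with 3 called when adjusted over the list alone. The mitochondrial list's median was -0.08 (adjusted p = 0.284). Of 23 tested p53 targets, 10 rose, 5 fell and 8 were not called, with 15 called when adjusted over the list alone. The p53 list's median was -0.01, the mean 0.28 and the tested direction higher (adjusted p = 0.322). CCNG1 (0.98, 0.49 with its window's median removed) and EDA2R (1.91) rose. Of 21 tested immediate early and stress genes, 9 rose, 6 fell and 6 were not called, with 16 called when adjusted over the list alone. The immediate early list's median was 0.12 (adjusted p = 0.264). ATF3 (1.73) and DUSP1 (1.09, 0.50 with its window's median removed) rose.

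Antigen presentation genes fell. Of 22 tested genes of MHC class I and II, 0 rose, 18 fell and 4 were not called, with 18 called when adjusted over the list alone. The MHC list's median was -0.52 (adjusted p = 3.6e-09, and adjusted p = 0.0391 with an estimated correlation). The class II transactivator CIITA fell to 32.3 ± 0.358 against 71.1 ± 2.21, log2 change -1.12, adjusted p = 4.4e-09, the invariant chain CD74 to 2627 ± 48.4 against 4818 ± 115, log2 change -0.87, and HLA-DMB to 29.8 ± 1.35 against 60.1 ± 3.46, log2 change -1.0. Reads of HLA genes depend on the alleles in the reference. Of 23 tested NF-kB targets, 5 rose, 13 fell and 5 were not called, with 19 called when adjusted over the list alone. The NF-kB list's median was -0.14 (adjusted p = 0.0462, and adjusted p = 0.162 with an estimated correlation). This call was lost without TKO replicate 1 (0.0598), WT replicate 2 (0.0514) or WT replicate 3 (0.0566), the adjusted p in parentheses. TNFAIP2 (-0.78) and PLEK (-1.19) fell, and NFKB2 (0.47, 0.11 with its window's median removed) and the chemokine CXCL10 (1.07) rose. Of 33 tested interferon response genes, 6 rose, 14 fell and 13 were not called, with 20 called when adjusted over the list alone. The interferon list's median was -0.10 (adjusted p = 0.138). HERC5 (1.64) rose, and IRF1 (-0.66) and TAP1 (-0.40) fell.

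Few markers of other cell types were expressed. Of 5 tested T and NK cell markers, 1 rose, 3 fell and 1 was not called, with 4 called when adjusted over the list alone. The T cell list's median was -0.69 (adjusted p = 0.540). CD7 rose to 18 ± 0.868 against 3.90 ± 0.0890, log2 change 2.07. Fibroblast, epithelial, and erythroid or endothelial markers had 4, 3 and 2 tested genes, too few for a test of the list. Of these 2, 1 and 0 rose and 1, 2 and 2 fell, and 4, 3 and 2 were called when adjusted over the list alone. Their medians were 0.09, -0.79 and -1.88. KRT7 measured 0.859 ± 0.120 against 3.76 ± 0.507 and PECAM1 0.295 ± 0.234 against 1.74 ± 0.387 FPKM. Of 14 myeloid markers 0 passed the filter on low values.

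In total 7152 of 14391 tested genes (49.7%) were called between WT and TKO by limma after Benjamini-Hochberg adjustment, 3706 higher and 3446 lower in WT, and 948 changed at least 2-fold. All 3 WT libraries lay on one side of all 3 TKO libraries in 60.4% of tested genes, where chance gives 10%, and in each changed gene named above. Camera with a preset correlation called 11 of 30 lists. Of these, 6 were called also with an estimated correlation: PRC2, cell cycle, MHC, unfolded protein response, hypoxia and cholesterol synthesis. Every comparison rests on 1 cell line, with the number of independent vector lines not given in the sources used here.

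**Figure D3:**
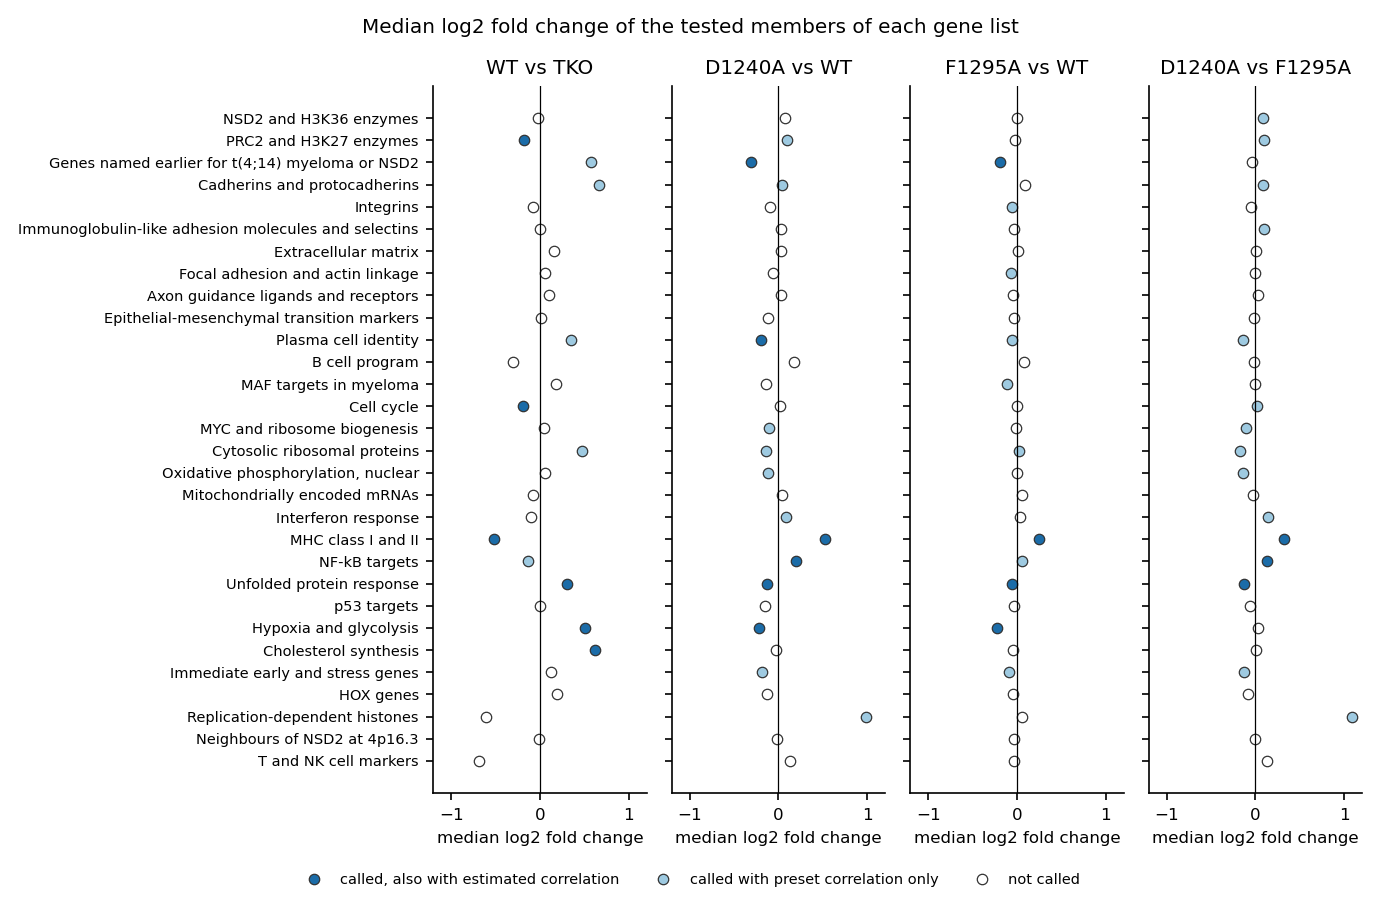
Median log2 change (horizontal) of the tested genes of each of 30 lists (vertical) in WT vs TKO, D1240A vs WT, F1295A vs WT and D1240A vs F1295A. Dark points mark lists called also with an estimated correlation, light points those called with the preset correlation alone and open points those not called; the MHC list has medians of -0.52, 0.53, 0.25 and 0.32.

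Parts of chromosomes differed as blocks between TKO and all 3 vector lines. Along the genome, 273 windows of 50 neighbouring tested genes were compared. In WT against TKO, 18 windows (6.59%) had a median log2 change beyond 0.3 in size, and the largest in 100 shuffles of the gene order was 0.24. Of these, 11 were lower in WT: 6 windows of the X chromosome, from -0.41 to -0.92, and windows on chromosome 21 (-0.42 and -0.36), chromosome 7 (-0.42 and -0.34) and chromosome 8 (-0.39). The lowest spans 3604370 to 23766475 on X, where 47 of 50 genes were called. The 7 higher windows lie on chromosome 10 (0.30, 0.34 and 0.41), chromosome 5 (0.46 and 0.56) and chromosome 13 (0.48 and 0.59). All 18 passed 0.3 with the same sign in D1240A and in F1295A against TKO, where 19 windows passed in each. In D1240A vs WT, F1295A vs WT and D1240A vs F1295A, 0 windows passed, with medians from -0.10 to 0.21, -0.09 to 0.06 and -0.09 to 0.16. Inside the 18 windows 77.2% of genes were called between WT and TKO, against 47.8% elsewhere, and these windows hold 900 genes. With each window's median removed, 5781 of the 7152 genes called between WT and TKO (80.8%) were called the same way, and L1CAM, which lies in an X window, changed by -1.67 instead of -2.18.

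**Figure D4:**
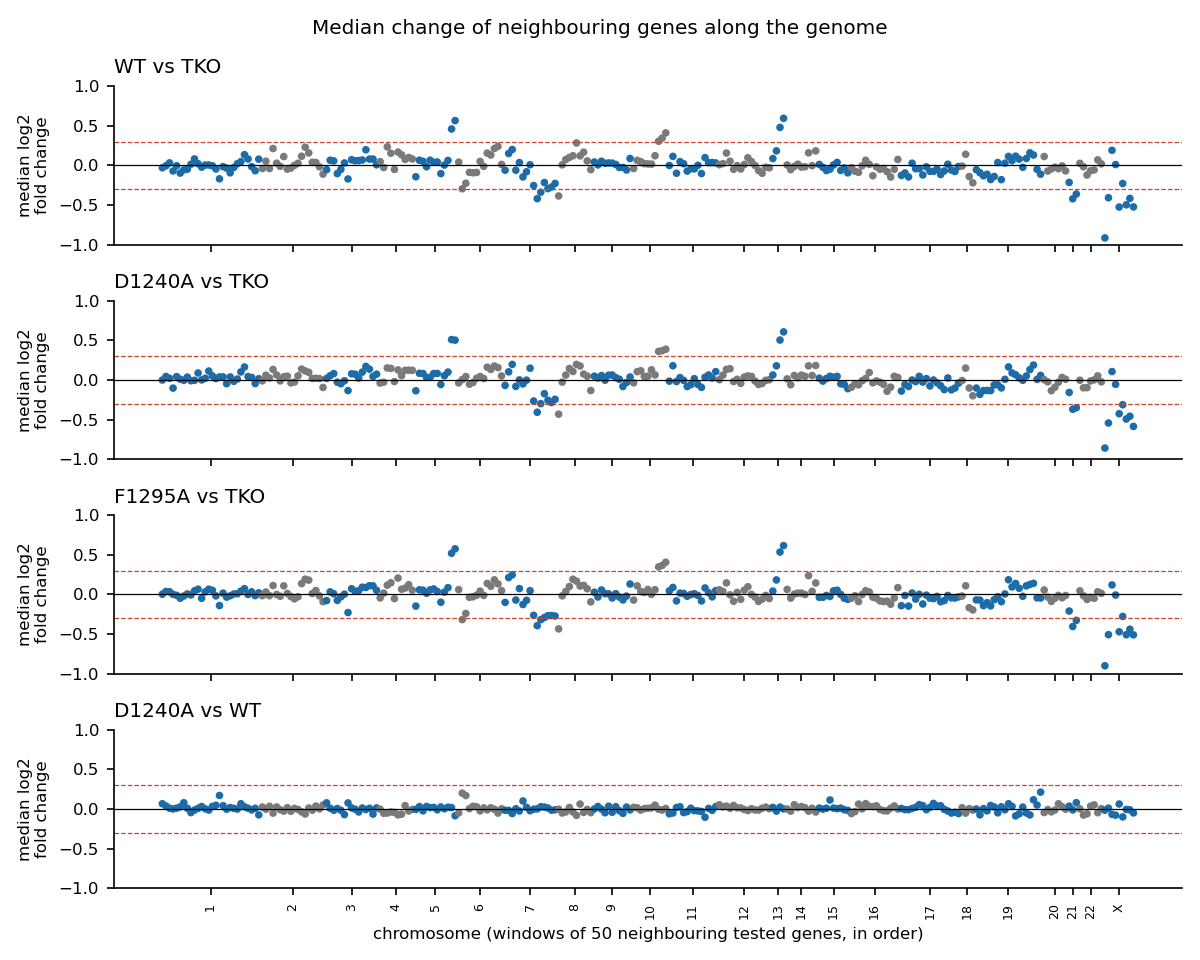
Median log2 change (vertical) of windows of 50 neighbouring tested genes in genome order (horizontal, by chromosome), for WT, D1240A and F1295A against TKO and for D1240A against WT; dashed lines mark 0.3 and -0.3. The 3 comparisons with TKO share the same blocks, from -0.92 to 0.59 in WT vs TKO, and D1240A vs WT has 0 windows beyond the lines.

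D1240A against WT asks what the substitution changes where NSD2 is expressed. Antigen presentation was higher in D1240A. Of 22 tested MHC genes, 15 rose, 0 fell and 7 were not called, with 16 called when adjusted over the list alone. The MHC list's median was 0.53 (adjusted p = 1.5e-19, and adjusted p = 0.00661 with an estimated correlation). CIITA measured 65.0 ± 2.96 against 32.3 ± 0.358, log2 change 1.0, adjusted p = 4.0e-07. HLA-DRB1 rose to 290.3 ± 13.1 against 155 ± 7.76, log2 change 0.90, and HLA-DOA, which modulates class II loading, to 20.1 ± 0.685 against 8.0 ± 0.762, log2 change 1.28. NF-kB targets rose too. Of 23 tested NF-kB targets, 12 rose, 1 fell and 10 were not called, with 13 called when adjusted over the list alone. The NF-kB list's median was 0.20 (adjusted p = 8.5e-07, and adjusted p = 0.00661 with an estimated correlation). The apoptosis inhibitor BIRC3 rose to 131 ± 4.99 against 90.5 ± 1.11, log2 change 0.53, and TNFAIP3 (0.41) and CXCL10 (1.06) rose. Of single genes, TNFRSF18 measured 11.7 ± 1.3 against 3.82 ± 0.614, log2 change 1.5, adjusted p = 4.0e-06, and SOCS1, a suppressor of cytokine signalling, 20.8 ± 0.955 against 7.11 ± 1.03, log2 change 1.49, adjusted p = 1.3e-06. LAMP5 measured 9.99 ± 0.637 against 3.33 ± 0.336, log2 change 1.45. Of 33 tested interferon response genes, 10 rose, 3 fell and 20 were not called, with 14 called when adjusted over the list alone. The interferon list's median was 0.08, or -0.02 on the values as deposited (adjusted p = 0.0178, and adjusted p = 0.0741 with an estimated correlation). SAMD9L (0.49) rose and HERC5 (-0.36) fell.

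Adhesion genes changed both ways in D1240A. L1CAM (ENSG00000198910, chromosome X, 153861514 to 153886174) rose to 8.63 ± 0.399 against 3.33 ± 0.581, log2 change 1.27, adjusted p = 1.4e-05. CD48 rose to 38.8 ± 1.56 against 27.6 ± 0.379, log2 change 0.48, ICAM1 to 30.0 ± 0.324 against 22.2 ± 0.566, log2 change 0.43, and NRCAM to 13.2 ± 0.806 against 8.79 ± 0.419, log2 change 0.57. Of 35 tested immunoglobulin-like adhesion molecules, 9 rose, 6 fell and 20 were not called, with 18 called when adjusted over the list alone. The immunoglobulin-like list's median was 0.03, or -0.07 on the values as deposited (adjusted p = 0.283, and adjusted p = 0.00404 by Fisher's exact test). CDH17 measured 107 ± 3.46 against 80.5 ± 1.45, log2 change 0.41, adjusted p = 1.9e-05, or adjusted p = 0.0580 on the values as deposited, and the protocadherin PCDH10 (0.51) rose. Of 15 tested cadherins, 5 rose, 1 fell and 9 were not called, with 7 called when adjusted over the list alone. The cadherin list's median was 0.04, or -0.02 on the values as deposited (adjusted p = 0.0251, and adjusted p = 0.231 with an estimated correlation, and adjusted p = 0.0741 by Fisher's exact test). That call was lost without WT replicate 2 (0.0599). Of 13 tested integrins, 1 rose, 4 fell and 8 were not called, with 6 called when adjusted over the list alone. The integrin list's median was -0.10 (adjusted p = 0.0856, and adjusted p = 0.118 by Fisher's exact test). ITGB7 (-0.50) and ITGB1 (-0.26) fell. Of 52 tested focal adhesion and actin genes, 10 rose, 16 fell and 26 were not called, with 29 called when adjusted over the list alone. The focal adhesion list's median was -0.07 (adjusted p = 0.112, and adjusted p = 4.4e-06 by Fisher's exact test). LPXN (0.88) rose, and ZYX (-0.65), ENAH (-1.32) and EVL (-0.48) fell. Of 30 tested matrix genes, 6 rose, 8 fell and 16 were not called, with 16 called when adjusted over the list alone. The matrix list's median was 0.02, or -0.06 on the values as deposited, the mean 0.02 and the tested direction lower (adjusted p = 0.918, and adjusted p = 0.00154 by Fisher's exact test). COL6A1 (1.14) rose and MATN2 (-0.47) fell.

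Myeloma, plasma cell and stress genes fell in D1240A. Of 18 tested genes tied to t(4;14) or NSD2, 0 rose, 10 fell and 8 were not called, with 11 called when adjusted over the list alone. The t(4;14) list's median was -0.31 (adjusted p = 8.6e-08, and adjusted p = 0.0204 with an estimated correlation). CA2 measured 3.58 ± 0.0197 against 8.76 ± 0.547, log2 change -1.18, adjusted p = 4.5e-06. RRAS2 fell to 1.65 ± 0.280 against 4.69 ± 0.185, log2 change -1.28, MYC to 170.2 ± 7.11 against 238 ± 9.15, log2 change -0.48, and FGFR3 to 391 ± 4.12 against 505 ± 2.89, log2 change -0.37. Of 20 tested plasma cell genes, 2 rose, 12 fell and 6 were not called, with 14 called when adjusted over the list alone. The plasma cell list's median was -0.20 (adjusted p = 2.1e-05, and adjusted p = 0.0407 with an estimated correlation). TXNDC5 (-0.51), XBP1 (-0.29) and PIM2 (-0.27) fell. Of 33 tested unfolded protein response genes, 0 rose, 16 fell and 17 were not called, with 16 called when adjusted over the list alone. The unfolded protein list's median was -0.13 (adjusted p = 1.7e-09, and adjusted p = 0.00661 with an estimated correlation). SESN2 fell to 10.6 ± 0.70 against 21.2 ± 0.873, log2 change -0.96, as did DDIT3 (-0.67) and HERPUD1 (-0.35). Of 33 tested hypoxia and glycolysis genes, 2 rose, 20 fell and 11 were not called, with 24 called when adjusted over the list alone. The hypoxia list's median was -0.22 (adjusted p = 1.8e-09, and adjusted p = 0.00661 with an estimated correlation). DDIT4 fell to 67.2 ± 2.71 against 122 ± 0.506, log2 change -0.85, as did HK2 (-0.41) and LDHA (-0.30). Of 21 tested immediate early and stress genes, 0 rose, 9 fell and 12 were not called, with 12 called when adjusted over the list alone. The immediate early list's median was -0.18 (adjusted p = 0.00225, and adjusted p = 0.109 with an estimated correlation). JUN (-1.06) and ATF3 (-1.21) fell. Of single genes, the carboxypeptidase CPVL measured 3.83 ± 0.629 against 12.2 ± 0.0667, log2 change -1.57, adjusted p = 2.8e-06. TMSB15A, which has a close paralog, fell by 1.57, the hormone subunit INHBE by 1.55, and RAI14 by 1.43. The receptor GPR171 fell by 1.88. The antisense transcript PCED1B-AS1 fell by 1.23, and the strand setting of the libraries is not stated.

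Growth gene lists were called lower, by small amounts. Of 77 tested ribosomal protein genes, 0 rose, 35 fell and 42 were not called, with 57 called over the list alone. The list's median was -0.14 (adjusted p = 4.2e-14, or 0.318 with an estimated correlation). RPL35 measured 1353 ± 23.4 against 1642 ± 64.8, log2 change -0.28. Of 74 tested genes of oxidative phosphorylation, 0 rose, 30 fell and 44 were not called, with 36 called when adjusted over the list alone. The oxidative phosphorylation list's median was -0.12 (adjusted p = 3.6e-07, and adjusted p = 0.405 with an estimated correlation). Of 41 tested genes of MYC and ribosome biogenesis, 0 rose, 16 fell and 25 were not called, with 18 called when adjusted over the list alone. The MYC list's median was -0.11 (adjusted p = 5.5e-06, and adjusted p = 0.107 with an estimated correlation). Of 14 tested PRC2 and H3K27 genes, 3 rose, 1 fell and 10 were not called, with 5 called when adjusted over the list alone. The PRC2 list's median was 0.10, or -0.02 on the values as deposited (adjusted p = 0.0318, and adjusted p = 0.107 with an estimated correlation). That call was lost without WT replicate 1 (0.0717) or D1240A replicate 1 (0.0517), with window medians removed (adjusted p = 0.403) and on the values as deposited (0.408). The histone values depend on D1240A replicate 2. Of 34 tested histones, 2 rose, 0 fell and 32 were not called, with 1 called when adjusted over the list alone. The list's median was 0.98 (adjusted p = 3.5e-05, or 0.490 with an estimated correlation). Without that library the median was 0.18 and the adjusted p 0.0502. HIST1H2AC measured 17.5 ± 4.70 against 11.2 ± 0.243, log2 change 0.59, or 0.39 without that library.

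Between D1240A and WT 2732 genes (19.0%) were called, 1115 higher and 1617 lower in D1240A, and 81 changed at least 2-fold. The libraries of one group lay on one side of those of the other in 35.3% of tested genes, where chance gives 10%, and in each changed gene named for this comparison. Without WT replicate 1 the count was 1716, and without D1240A replicate 2 it was 2224. On the values as deposited it was 1608, and 15.5% of the calls were higher in D1240A instead of 40.8%, with all genes shifted by a median of -0.10. Camera called 14 of 30 lists, 6 of them also with an estimated correlation: t(4;14) genes, plasma cell, MHC, NF-kB, unfolded protein response and hypoxia.

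F1295A against WT asks the same of the other substitution, and fewer genes were called. Hypoxia and glycolysis genes fell. Of 33 tested hypoxia genes, 0 rose, 15 fell and 18 were not called, with 26 called when adjusted over the list alone. The hypoxia list's median was -0.22 (adjusted p = 8.5e-25, and adjusted p = 4.0e-04 with an estimated correlation). DDIT4 measured 73.4 ± 3.21 against 122 ± 0.506, log2 change -0.73, adjusted p = 2.1e-05. The prolyl hydroxylase P4HA1 fell to 8.08 ± 0.206 against 12.3 ± 0.582, log2 change -0.58, the glycolytic regulator PFKFB4 to 0.802 ± 0.0906 against 2.33 ± 0.201, log2 change -1.12, and NDRG1 to 27.2 ± 1.85 against 39.1 ± 1.25, log2 change -0.52. Of 33 tested unfolded protein response genes, 0 rose, 10 fell and 23 were not called, with 13 called when adjusted over the list alone. The unfolded protein list's median was -0.06 (adjusted p = 2.4e-05, and adjusted p = 0.0421 with an estimated correlation). SESN2 measured 14 ± 0.420 against 21.2 ± 0.873, log2 change -0.58, adjusted p = 6.7e-04, and CHAC1 13.4 ± 0.490 against 19.3 ± 0.425, log2 change -0.51. Of 18 tested genes tied to t(4;14) or NSD2, 0 rose, 6 fell and 12 were not called, with 10 called when adjusted over the list alone. The t(4;14) list's median was -0.19 (adjusted p = 9.5e-12, and adjusted p = 0.00848 with an estimated correlation). CA2 fell to 5.47 ± 0.259 against 8.76 ± 0.547, log2 change -0.63, and the receptor MET (-1.06) fell. MHC genes rose. Of 22 tested MHC genes, 13 rose, 0 fell and 9 were not called, with 15 called when adjusted over the list alone. The MHC list's median was 0.25 (adjusted p = 2.9e-23, and adjusted p = 0.00612 with an estimated correlation). HLA-DRB1 measured 223 ± 4.96 against 155 ± 7.76, log2 change 0.53, adjusted p = 7.8e-05, and HLA-DQA1 91.9 ± 2.65 against 56.3 ± 3.47, log2 change 0.70.

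Of single genes in F1295A, LAMP5 rose to 7.66 ± 0.668 against 3.33 ± 0.336, log2 change 1.09, adjusted p = 7.0e-05. TNFRSF18 rose to 7.79 ± 0.694 against 3.82 ± 0.614, log2 change 0.95, and COL6A1 to 4.91 ± 0.573 against 2.77 ± 0.247, log2 change 0.72. The transcription factor JDP2 fell to 3.13 ± 0.277 against 6.46 ± 0.751, log2 change -0.93, adjusted p = 0.00336, and the chaperone CLGN to 5.93 ± 0.295 against 10.7 ± 0.392, log2 change -0.80, adjusted p = 7.0e-05. TMSB15A fell to 7.75 ± 0.780 against 14.1 ± 1.31, log2 change -0.83. Among adhesion genes, CDH17 rose to 93.7 ± 2.56 against 80.5 ± 1.45, log2 change 0.22, CD48 to 36.7 ± 0.930 against 27.6 ± 0.379, log2 change 0.41, and the actin regulator ENAH fell to 1.2 ± 0.122 against 2.98 ± 0.0485, log2 change -1.03. Of 15 tested cadherins, 2 rose, 0 fell and 13 were not called, with 3 called when adjusted over the list alone. The cadherin list's median was 0.09 (adjusted p = 0.239, and adjusted p = 0.129 by Fisher's exact test). Of 35 tested immunoglobulin-like adhesion molecules, 2 rose, 3 fell and 30 were not called, with 8 called when adjusted over the list alone. The immunoglobulin-like list's median was -0.04 (adjusted p = 0.865, and adjusted p = 0.00868 by Fisher's exact test). Of 52 tested focal adhesion and actin genes, 2 rose, 5 fell and 45 were not called, with 17 called when adjusted over the list alone. The focal adhesion list's median was -0.06 (adjusted p = 0.00436, and adjusted p = 0.223 with an estimated correlation, and adjusted p = 0.00198 by Fisher's exact test). Of 13 tested integrins, 0 rose, 2 fell and 11 were not called, with 5 called when adjusted over the list alone. The integrin list's median was -0.05 (adjusted p = 0.0414, and adjusted p = 0.139 with an estimated correlation, and adjusted p = 0.107 by Fisher's exact test). The integrin call was lost without WT replicate 2 (0.136), WT replicate 3 (0.172) or F1295A replicate 3 (0.128). On the values as deposited the adjusted p was 0.580 for CDH17 and 0.0759 for CD48.

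Further lists were called in F1295A against WT, none of them with an estimated correlation. Of 20 tested plasma cell genes, 0 rose, 7 fell and 13 were not called, with 8 called when adjusted over the list alone. The plasma cell list's median was -0.06 (adjusted p = 0.00310, and adjusted p = 0.139 with an estimated correlation). PIM2 (-0.18) and TXNDC5 (-0.23) fell, with adjusted p on the values as deposited of 0.372 for PIM2 and 0.242 for TXNDC5. Of 21 tested immediate early and stress genes, 0 rose, 5 fell and 16 were not called, with 9 called when adjusted over the list alone. The immediate early list's median was -0.09 (adjusted p = 0.0114, and adjusted p = 0.162 with an estimated correlation). Of 10 tested MAF targets, 0 rose, 2 fell and 8 were not called, with 4 called when adjusted over the list alone. The MAF list's median was -0.11 (adjusted p = 0.0471, and adjusted p = 0.148 with an estimated correlation). This was lost without WT replicate 1 (0.0504), WT replicate 2 (0.0531), WT replicate 3 (0.111), F1295A replicate 2 (0.120) or F1295A replicate 3 (0.0582). Of 23 tested NF-kB targets, 1 rose, 0 fell and 22 were not called, with 2 called when adjusted over the list alone. The NF-kB list's median was 0.05 (adjusted p = 0.0471, and adjusted p = 0.154 with an estimated correlation). This was lost without WT replicate 2 (0.0933), WT replicate 3 (0.115), F1295A replicate 1 (0.148) or F1295A replicate 3 (0.050). Of 77 tested ribosomal protein genes, 0 rose, 0 fell and 77 were not called, with 0 called when adjusted over the list alone. The ribosomal protein list's median was 0.02, or -0.01 on the values as deposited (adjusted p = 0.0491, and adjusted p = 0.899 with an estimated correlation). This was lost without WT replicate 2 (0.0933), WT replicate 3 (0.513), F1295A replicate 2 (0.629) or F1295A replicate 3 (0.125). With the values as deposited the adjusted p was 0.124 for plasma cell genes, 0.101 for MAF targets, 0.124 for NF-kB targets, 0.101 for integrins and 0.255 for ribosomal protein genes. Of 34 tested histones, 0 rose, 0 fell and 34 were not called, with 0 called when adjusted over the list alone. The histone list's median was 0.06 (adjusted p = 0.534). Without D1240A replicate 2, which enters the pooled spread, 4 histones rose and the adjusted p was 0.0398.

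Between F1295A and WT 388 genes (2.7%) were called, 126 higher and 262 lower in F1295A, and 11 changed at least 2-fold, while 2331 had an unadjusted p under 0.05. The libraries of the groups were separated in 22.9% of tested genes, where chance gives 10%, and in each changed gene named for this comparison. The count was 150 without WT replicate 1, 228 without WT replicate 2, 173 without WT replicate 3, 168 without F1295A replicate 2 and 207 without F1295A replicate 3. Without rescaling it was 89, and 19.1% of the calls were higher in F1295A instead of 32.5%. Camera called 11 of 30 lists, or 7 without WT replicate 2, and 4 of the 11 also with an estimated correlation.

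D1240A against F1295A tests where the mutants differ from each other. Antigen presentation and NF-kB targets were higher in D1240A. Of 22 tested MHC genes, 15 rose, 0 fell and 7 were not called, with 15 called when adjusted over the list alone. The MHC list's median was 0.32 (adjusted p = 2.8e-14, and adjusted p = 0.0205 with an estimated correlation). CIITA measured 65.0 ± 2.96 against 40.3 ± 2.59, log2 change 0.68, adjusted p = 3.6e-05. Of 23 tested NF-kB targets, 8 rose, 0 fell and 15 were not called, with 11 called when adjusted over the list alone. The NF-kB list's median was 0.13 (adjusted p = 7.8e-08, and adjusted p = 0.0148 with an estimated correlation). CXCL10 measured 17.5 ± 0.564 against 9.73 ± 0.931, log2 change 0.82, adjusted p = 4.8e-04. SOCS1 measured 20.8 ± 0.955 against 11.5 ± 0.773, log2 change 0.83, adjusted p = 3.4e-04, and L1CAM 8.63 ± 0.399 against 4.72 ± 0.554, log2 change 0.81, adjusted p = 0.00172. The adhesion molecule ALCAM measured 3.99 ± 0.0963 against 2.38 ± 0.0155, log2 change 0.64. Unfolded protein response genes were lower in D1240A. Of 33 tested unfolded protein response genes, 0 rose, 11 fell and 22 were not called, with 15 called when adjusted over the list alone. The unfolded protein list's median was -0.12 (adjusted p = 2.8e-08, and adjusted p = 0.0205 with an estimated correlation). DDIT3 (-0.35) fell. CPVL measured 3.83 ± 0.629 against 7.14 ± 0.625, log2 change -0.83, adjusted p = 0.00139. TMSB15A was lower by a log2 change of -0.74, caveolin, CAV2, of -0.65, CA2 of -0.55, and the matrix protein MATN2 of -0.33.

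Growth and plasma cell lists were called lower in D1240A than in F1295A. Of 77 tested ribosomal protein genes, 0 rose, 31 fell and 46 were not called, with 72 called when adjusted over the list alone. The ribosomal protein list's median was -0.17 (adjusted p = 2.0e-29, and adjusted p = 0.166 with an estimated correlation). Of 74 tested genes of oxidative phosphorylation, 0 rose, 17 fell and 57 were not called, with 38 called when adjusted over the list alone. The oxidative phosphorylation list's median was -0.14 (adjusted p = 6.9e-16, and adjusted p = 0.214 with an estimated correlation). Of 41 tested genes of MYC and ribosome biogenesis, 0 rose, 10 fell and 31 were not called, with 20 called when adjusted over the list alone. The MYC list's median was -0.10 (adjusted p = 6.2e-10, and adjusted p = 0.0539 with an estimated correlation). Of 20 tested plasma cell genes, 0 rose, 8 fell and 12 were not called, with 12 called when adjusted over the list alone. The plasma cell list's median was -0.15 (adjusted p = 1.4e-04, and adjusted p = 0.0646 with an estimated correlation). TXNDC5 measured 328 ± 5.76 against 399 ± 2.11, log2 change -0.28, or adjusted p = 0.0812 on the values as deposited. Of 21 tested immediate early and stress genes, 0 rose, 2 fell and 19 were not called, with 3 called when adjusted over the list alone. The list's median was -0.13 (adjusted p = 0.0125, or 0.176 with an estimated correlation). Of 15 tested cadherins, 4 rose, 0 fell and 11 were not called, with 4 called when adjusted over the list alone. The cadherin list's median was 0.09, or -0.00 on the values as deposited (adjusted p = 0.0106, and adjusted p = 0.176 with an estimated correlation, and adjusted p = 0.0300 by Fisher's exact test). In the cadherin list 1 gene rose without D1240A replicate 2 (median 0.08). Histone values again depend on that library. Of 34 tested histones 0 were called, also when adjusted over the list alone. The list's median was 1.09 (adjusted p = 4.6e-06, or 0.543 with an estimated correlation). Without that library the median was 0.07 and the adjusted p 0.547.

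Further lists were called higher in D1240A than in F1295A, none of them with an estimated correlation. Of 20 tested H3K36 genes, 5 rose, 0 fell and 15 were not called, with 8 called when adjusted over the list alone. The list's median was 0.08, or -0.01 on the values as deposited (adjusted p = 0.00324, or 0.149 with an estimated correlation). The list holds NSD2 itself (250.2 against 164 FPKM) and was not tested without it. Only 1 gene rose without D1240A replicate 2 (adjusted p of the list 0.00763). Of 14 tested PRC2 and H3K27 genes 0 were called, or 5 when adjusted over the list alone. The list's median was 0.09 (adjusted p = 0.00460, or 0.0589 with an estimated correlation). Of 35 tested immunoglobulin-like adhesion molecules, 6 rose, 3 fell and 26 were not called, with 9 called when adjusted over the list alone. The list's median was 0.10 (adjusted p = 0.0299, or 0.0811 with an estimated correlation and 7.2e-04 by Fisher's exact test). This was lost without D1240A replicate 1 (0.0530), D1240A replicate 3 (0.0736) or F1295A replicate 1 (0.0796). Of 33 tested interferon response genes, 5 rose, 1 fell and 27 were not called, with 10 called when adjusted over the list alone. The list's median was 0.14 (adjusted p = 0.0175, or 0.0767 with an estimated correlation). This was lost without D1240A replicate 1 (0.0765). Of 47 tested cell cycle genes, 4 rose, 0 fell and 43 were not called, with 4 called when adjusted over the list alone. The list's median was 0.02, or -0.07 on the values as deposited (adjusted p = 0.0364, or 0.295 with an estimated correlation). This was lost without D1240A replicate 1 (0.186) or F1295A replicate 3 (0.0541). On the values as deposited the adjusted p was 0.0945 for the H3K36 list, 0.148 for the PRC2 list and 0.894 for the cell cycle list. A total of 880 genes (6.11%) were called, 417 higher and 463 lower in D1240A, and 7 changed at least 2-fold. The groups were separated in 24.1% of tested genes, where chance gives 10%. The balance turned to more higher than lower calls, 208 of 392 without D1240A replicate 2, 213 of 424 without D1240A replicate 3, 169 of 307 without F1295A replicate 2 and 205 of 348 without F1295A replicate 3. It did so too with no filter (244 of 438) and with only these groups fitted (73 of 105). On the values as deposited 63 genes were called. Camera called 15 of 30 lists, and 3 of them also with an estimated correlation: MHC, NF-kB and unfolded protein response.

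D1240A and F1295A against TKO give the change of each mutant from the same starting cells. In D1240A, LRMP measured 31.8 ± 1.10 against 0.0288 ± 0.0288, log2 change 5.93, adjusted p = 1.7e-14, and CDH17 107 ± 3.46 against 6.68 ± 0.197, log2 change 3.90, adjusted p = 1.7e-14. POPDC3 reached 26.7 ± 1.28 against 0.224 ± 0.0467, log2 change 5.23, and CDH2 9.57 ± 0.291 against 1.03 ± 0.220, log2 change 2.73. ADTRP fell to 1.13 ± 0.175 against 22 ± 0.258, log2 change -3.79, and the tetraspanin CD9 to 3.54 ± 0.419 against 26.4 ± 0.654, log2 change -2.74. In F1295A, LRMP measured 26.8 ± 1.40 against 0.0288 ± 0.0288, log2 change 5.69, adjusted p = 2.8e-14, and the actin regulator BAIAP2 63.0 ± 3.87 against 3.77 ± 0.650, log2 change 3.90, adjusted p = 6.3e-11. POPDC3 reached 26.9 ± 0.469 against 0.224 ± 0.0467, log2 change 5.25, CDH17 93.7 ± 2.56 against 6.68 ± 0.197, log2 change 3.71, and CDH2 9.12 ± 0.136 against 1.03 ± 0.220, log2 change 2.66. TRAF3IP3 fell to 11.8 ± 0.95 against 65.8 ± 3.78, log2 change -2.43, and CD9 to 4.72 ± 0.848 against 26.4 ± 0.654, log2 change -2.38. HBE1 was listed at 7.90, 7.06 and 9.10 FPKM in D1240A and at 6.84, 7.17 and 5.68 in F1295A, where TKO was listed at 0. MAGEA3 was listed at 8.09, 8.90 and 8.47 FPKM in D1240A and at 7.41, 7.59 and 7.46 in F1295A.

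Cholesterol synthesis genes rose against TKO in both mutants. In D1240A, 20 rose, 2 fell and 1 was not called, with 22 called when adjusted over the list alone. The cholesterol list's median was 0.53 (adjusted p = 1.2e-09, and adjusted p = 0.0144 with an estimated correlation). In F1295A, 19 rose, 1 fell and 3 were not called, with 20 called when adjusted over the list alone. The cholesterol list's median was 0.59 (adjusted p = 3.4e-09, and adjusted p = 0.0169 with an estimated correlation). INSIG1 rose by 1.07 in D1240A and 0.97 in F1295A. The cadherin list was called higher in both. In D1240A, 9 rose, 1 fell and 5 were not called, with 10 called when adjusted over the list alone. The cadherin list's median was 0.99 (adjusted p = 1.3e-04, and adjusted p = 0.0954 with an estimated correlation). In F1295A, 9 rose, 3 fell and 3 were not called, with 12 called when adjusted over the list alone. The cadherin list's median was 0.88 (adjusted p = 0.00279, and adjusted p = 0.155 with an estimated correlation). Unfolded protein response genes rose in both. In D1240A, 17 rose, 1 fell and 15 were not called, with 18 called when adjusted over the list alone. The unfolded protein list's median was 0.14, or -0.01 on the values as deposited (adjusted p = 1.3e-04, and adjusted p = 0.0688 with an estimated correlation). In F1295A, 23 rose, 3 fell and 7 were not called, with 27 called when adjusted over the list alone. The unfolded protein list's median was 0.27 (adjusted p = 1.3e-07, and adjusted p = 0.0272 with an estimated correlation). Cell cycle genes fell in both. In D1240A, 2 rose, 27 fell and 18 were not called, with 29 called when adjusted over the list alone. The cell cycle list's median was -0.14 (adjusted p = 5.6e-06, and adjusted p = 0.0688 with an estimated correlation). In F1295A, 2 rose, 30 fell and 15 were not called, with 32 called when adjusted over the list alone. The cell cycle list's median was -0.20 (adjusted p = 5.4e-07, and adjusted p = 0.0425 with an estimated correlation). The PRC2 list was called lower in both. In D1240A, 0 rose, 5 fell and 9 were not called, with 5 called when adjusted over the list alone. The PRC2 list's median was -0.08 (adjusted p = 0.0379, and adjusted p = 0.119 with an estimated correlation). The D1240A call was lost without D1240A replicate 3 (0.0506) and with window medians removed (0.103). In F1295A, 0 rose, 8 fell and 6 were not called, with 8 called when adjusted over the list alone. The PRC2 list's median was -0.23 (adjusted p = 5.7e-04, and adjusted p = 0.0342 with an estimated correlation). Ribosomal protein and hypoxia lists were also called higher in both, and the t(4;14) and plasma cell lists in F1295A, none of them with an estimated correlation. Of the MHC genes in D1240A, 4 rose, 8 fell and 10 were not called, with 12 called when adjusted over the list alone. The MHC list's median was -0.04 (adjusted p = 0.566). Of the same genes in F1295A, 1 rose, 14 fell and 7 were not called, with 15 called when adjusted over the list alone. The MHC list's median was -0.26 (adjusted p = 1.7e-04, and adjusted p = 0.155 with an estimated correlation). Of 34 tested histones, 2 fell in D1240A and 3 in F1295A, and without D1240A replicate 2 these counts were 16 and 23.

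Against TKO, 6420 genes (44.6%) were called in D1240A, 3305 higher and 3115 lower, and 6582 (45.7%) in F1295A, 3413 higher and 3169 lower. At least 2-fold changes were 653 and 744. The groups were separated in 52.5% and 55.8% of tested genes, where chance gives 10%. On the values as deposited 29.4% instead of 51.5% of the D1240A calls were higher, with all genes shifted by a median of -0.12. Camera called 7 lists in D1240A, or 12 without TKO replicate 1, and 1 of the 7 also with an estimated correlation. In F1295A it called 10, and 4 of them also with an estimated correlation.

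Over all tested genes, the change of each mutant from TKO was compared with that of WT from TKO. A slope of 1 would mean the same change as in WT. After removing the part that library noise and the shared TKO libraries add, the slope was 0.786 for D1240A, from 0.776 to 0.803 when each library was left out, and 0.880 for F1295A, from 0.867 to 0.893. Genes are not independent replicates, so no p is given. Of the genes called in D1240A against TKO, 5056 were called the same way in WT against TKO and 55 the other way, where independent lists of that size would share 1597. For F1295A the counts were 5775 and 4, against 1638. Covariances of the changes were 0.236 and 0.262, against 0.0194 and 0.0198 in simulations of unchanged groups on shared controls. The shared TKO libraries add to these overlaps.

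**Figure D5:**
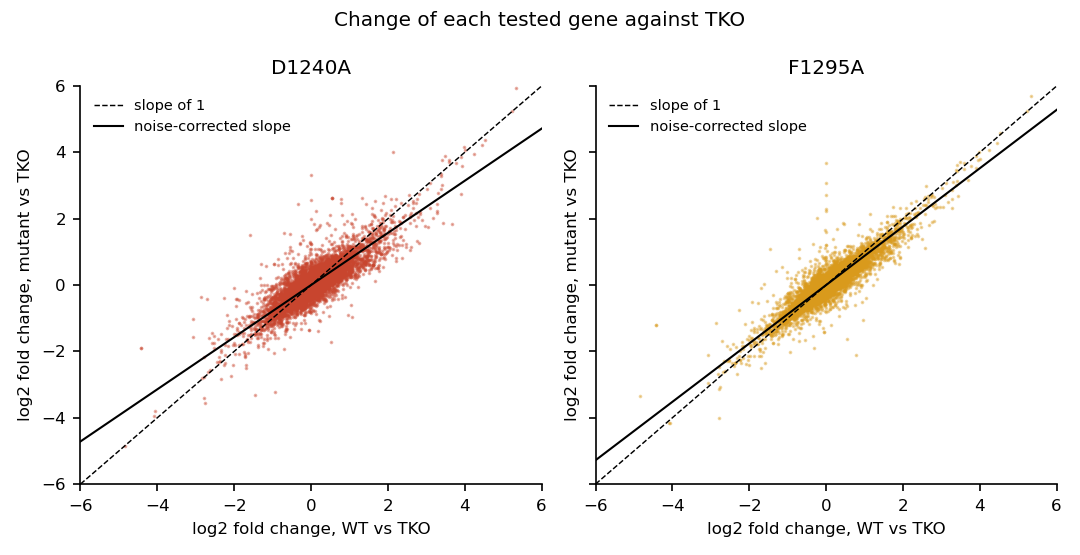
Log2 change of each mutant against TKO (vertical) over that of WT against TKO (horizontal), 1 point per tested gene, for D1240A and F1295A. The dashed line has slope 1 and the solid line the noise-corrected slope, 0.786 for D1240A and 0.880 for F1295A.

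The mutants' changes against WT were compared with each other and with the WT change. Of the 388 genes called in F1295A against WT, 344 (88.7%) were called the same way in D1240A against WT and 1 the other way, where independent lists would share 39.2. That number leaves out the shared WT libraries, which alone gave a simulated covariance of 0.0204 and correlation of 0.519 over all genes, against 0.0394 and 0.595 measured. That overlap was 140, 208 and 164 without WT replicates 1, 2 and 3, and 219, 155 and 195 without F1295A replicates 1, 2 and 3. DDIT4, SESN2, CA2, ENAH and TMSB15A fell in both mutants, and LAMP5, TNFRSF18 and COL6A1 rose in both. Of the D1240A calls against WT, 1807 (66.1%) ran opposite to the call in WT against TKO and 285 the same way, where independent lists give 683 opposite. For F1295A these were 292 (75.3%) and 41, against 97.6. The WT libraries stand in both comparisons with opposite sign, and the covariances were -0.0763 and -0.0496, against -0.0201 and -0.0198 simulated from that alone.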

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

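The tests of histones, of slopes, of NSD2 mRNA, of the vector and of calls with window medians removed and of windows between D1240A and WT were chosen only after the results they measure were seen, and the splits, the check of the library's label and the windows of WT against TKO before.

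D1240A replicate 2 held structural RNA, which was left out of the comparisons of genes as reported, above the level in the TKO libraries. Ribosomal RNA made up 51.4% of its FPKM sum (TKO 0.133% to 0.221%), and the sums of miscellaneous, small nuclear and small nucleolar RNAs were 118420, 90165 and 43022 FPKM. In TKO these were 1773 to 2129.5, 66.8 to 199 and 149.93 to 191.89. Long intergenic RNA, which was tested, also stood high, at 257696 FPKM against 4337 to 5793 in the other libraries. A library of another group under this label is argued against, since 98.0% of the 392 genes called between the mutants without it had the D1240A sign in it. Less complete poly(A) selection may be the cause, as histone mRNAs, which lack the tail, lay at a median of 3.97 above the other D1240A libraries. No biological explanation was tested.

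The 3 vector lines shared a change against TKO: of the genes called in WT against TKO, 65.7% were called the same way in both mutants. NSD2 protein in all 3 lines, and the vector, selection or passage, which all 3 also share, cannot be told apart, because no empty-vector line is among the groups. A copy-number difference between TKO and the vector lines may account for a part, since 6.59% of windows moved as blocks, though a regulatory change over a block, such as one of the X chromosome, was not tested. As the whole cause it is argued against, since 80.8% of the called genes were called the same way with the median of each window removed.

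The mutants' changes against WT ran opposite to the WT change, as if each mutant gave a part of it. Noise of the shared WT libraries is argued against, since the noise-corrected slopes stayed at or below 0.803 (D1240A) and 0.893 (F1295A) when each library was left out, and D1240A replicate 2 likewise, with a slope of 0.791 without it. A copy-number difference over a whole window is argued against by 0 windows beyond 0.3 between D1240A and WT. A smaller one was not tested. Less NSD2 mRNA in D1240A is argued against by its log2 change of 0.39 above WT. For F1295A, less NSD2 mRNA and a weaker protein cannot be told apart, since F1295A added 79.7% of the NSD2 mRNA that WT added to the TKO level, near its slope of 0.880. A loss of part of the protein's activity by the substitutions may remain for D1240A, but protein levels and independent lines were not measured here.

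With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. In the order WT vs TKO, D1240A vs WT, F1295A vs WT, D1240A vs TKO, F1295A vs TKO and D1240A vs F1295A, the real splits called 7152, 2732, 388, 6420, 6582 and 880 genes, and the highest other splits 1, 0, 0, 2, 3 and 4, so 1 of 10 splits was as large in each. For lists the real splits called 11, 14, 11, 7, 10 and 15 and the highest others 10, 9, 8, 8, 8 and 8. There 1 of 10 splits was as large, except 4 of 10 in D1240A vs TKO. In the other splits, which mix the groups, camera with the preset correlation thus called up to 8 to 10 lists.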

How the results depend on the processing

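Pseudocounts, library weights, structural RNAs kept, window medians removed and D1240A replicate 2 left out of comparisons without it were alternatives chosen after seeing the data, and the others were planned. The planned DESeq2 Wald test was not run, because the values are FPKM. The depth is unknown, so what depth limits cannot be given, and genes near 0.5 FPKM are limited by the filter. The 17 counts, slopes and overlaps had 242 alternatives, of which 199 stayed and 43 moved. Staying meant within 1.5 times a count. For a slope it meant a shift no larger than the width of its leave-one-out range, which left-out libraries themselves set. Of 780 alternatives of called lists 685 kept the call and 95 lost it. The 913 values of named genes had 14954 alternatives. Of these 14089 stayed on the same side of the threshold, 740 lost the call, 117 gained it and 8 changed sign. Sign was compared only where the value was called in the main or the alternative setting.

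In the order WT vs TKO, D1240A vs WT, F1295A vs WT, D1240A vs TKO, F1295A vs TKO and D1240A vs F1295A, a 2-fold minimum left 948, 81, 11, 653, 744 and 7 genes, by construction. On the values as deposited 1608 genes were called in D1240A vs WT, 89 in F1295A vs WT and 63 in D1240A vs F1295A, and 6 lists in F1295A vs WT and 11 in D1240A vs TKO. EZH2 then changed by -0.018 in D1240A vs WT. Library weights gave 618 genes in F1295A vs WT. D1240A vs F1295A gave 438 with no filter, 532 with the replicate block (277 higher) and 105 with only its groups fitted, where fewer libraries estimate the spread. Of these 105, 69.5% were higher in D1240A, against 47.4%. An estimated correlation called 6, 6, 4, 1, 4 and 3 lists, and fry 26, 24, 22 and 23 in WT vs TKO, D1240A vs WT, D1240A vs TKO and F1295A vs TKO, by testing each list without the other genes.

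With window medians removed, 7 changes against TKO changed sign: DNMT1 0.028 in WT, 0.099 in D1240A and 0.027 in F1295A, and in D1240A FLNA 0.0015, DKC1 0.042, NOP16 -0.070 and HOXA10 -0.061. Leaving out each library gave 1716 to 2843 genes in D1240A vs WT, 150 to 516 in F1295A vs WT and 307 to 1259 in D1240A vs F1295A, 7 to 12 lists in F1295A vs WT and 6 to 12 in D1240A vs TKO, and 140 to 439 genes shared by the calls of both mutants against WT. Except where fewer libraries or the construction explain it, the cause was not tested.

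Replicate numbers paired the samples weakly at most. Of 18 pairs of same-numbered libraries none correlated over 0.1 in deviation from the group means (-0.053 to 0.085). Yet 10 of 12 libraries correlated best with their own number, so a small effect shared by a number is not excluded. The replicate block called 6987, 2359, 273, 6182, 6356 and 532 genes in the same order.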

Other observations

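The tests in this part were chosen after the result was seen. Stress genes lower in both mutants than in WT, such as SESN2, DDIT4 and CHAC1, may share the regulator ATF4, which answers amino-acid shortage. Of a list of 34 amino-acid and ATF4 target genes, written after the stress genes were seen, 4 already among the picked genes were left out and 29 of the others were tested. In D1240A against WT their median was -0.21, with 17 lower, 1 higher (NUPR1, log2 change 1.01) and 27 below 0 (camera p = 1.5e-12, or 4.3e-05 with an estimated correlation). In F1295A against WT it was -0.11, with 7 lower and 26 below 0 (camera p = 3.2e-09, or 1.5e-04 with an estimated correlation). ATF4 protein and the amino-acid supply of the cultures were not measured here.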
